A study of Mus musculus with 20 samples.

How the data were processed

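Small RNA was sequenced from cauda epididymosomes, the extracellular vesicles of the distal epididymis, of 9-month-old male mice. Per the labels' protocols, sperm were removed by swim-up in M2 medium, cleared supernatant was ultracentrifuged at 120000 rcf for 2 h, and libraries were made with the NEBNext Small RNA kit. The Control group held 5 males left undisturbed and the MSUS group 5 males whose litters had unpredictable maternal separation for 3 h per day over 2 weeks (14 days) after birth, combined with unpredictable stress of the dams. The 10 libraries were sequenced in 2 runs, with and without selection of a size range that enriches for miRNAs, which gives 20 samples. Groups and animal numbers were taken from the sample titles. Control animals were 3, 5, 7, 9 and 11, and MSUS animals 2, 4, 6, 8 and 14. The labels do not say whether animals shared a litter, so the p-values measure the spread between these animals.

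The deposited values are estimated counts per annotated RNA in 2 tables, many of them not whole. Per the submitters' processing notes, the genome build was GRCm38 and the tools included STAR and edgeR. How reads were assigned to RNAs is not given in the sources used here. Totals per library ranged from 1872084 to 3647956 counts in the table labelled with size selection and from 215231 to 871461 in the table labelled without. Counts on mature miRNAs ranged from 234146 to 550396 and from 132139 to 575372. The labels of both tables conflict with their contents, as miRNAs took 10.9 to 17.0% of counts in the table labelled with size selection and 52.4 to 72.2% in the other. The tables are therefore named by their labels throughout, and any direction between them refers to the labels. The contrast of MSUS with Control is made within a table and does not depend on this.

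The tables held 72034 and 59035 features, of which 54796 were in both, and 940 and 868 features were mature miRNAs. Classes were taken from the feature identifiers and the transcript types they carry. The 352 names without a type all matched rRNA genes in the GENCODE vM21 annotation of GRCm38, which also gave the gene coordinates. miRNAs that share a mature sequence or a name are one feature, and copies of snRNA, rRNA and tRNA genes share reads, so that single copies are uncertain. Percentages of a library were computed from the estimated counts. Estimated counts were rounded to whole numbers before the count tests, which removed 0.0504 to 0.0992% of counts in the table labelled with size selection and 0.266 to 0.689% in the other.

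Differences between groups were tested with edgeR 4.0.16 in R 4.3.3: features kept by filterByExpr, TMM scaling, the robust quasi-likelihood test and Benjamini-Hochberg adjustment with a threshold of 0.05. For the miRNA tests the library size was the sum over miRNAs, and CPM of a miRNA are relative to its TMM-scaled miRNA total. Standard errors (SE) of log2 fold changes were derived from the quasi-likelihood F statistic. The tables were fitted separately, because the runs repeat the same animals. The comparison between tables used all 20 samples, the features present in both tables and condition as a covariate, and the difference of the MSUS effect between tables was an interaction term with animal as a block. Class percentages were compared by an exact two-sided permutation test between groups, which cannot go below 0.00794, and by an exact two-sided sign-flip test over the 10 animals between tables, which cannot go below 0.00195, with Benjamini-Hochberg adjustment over classes. The same animal stands behind each number in both tables, per the labels. Deviations from the group means of 231 miRNAs correlated at 0.488 to 0.776 between the 2 samples of an animal, each animal matched itself best in 10 of 10 cases, and the highest correlation between different animals was 0.409.

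Before the data were examined, 16 miRNA lists and 4 transcript lists were fixed: the let-7, miR-10/99/100, miR-34/449, miR-29 and miR-30 families, epithelial, blood cell, muscle and stroma, endothelial, liver and neural, and inflammation-related miRNAs, the X-linked male reproductive tract, miR-17/92, Dlk1-Dio3 and Sfmbt2 clusters, sperm miRNAs named by earlier studies of paternal stress and of MSUS, and transcripts of epididymal epithelium, sperm and spermatids, blood cells, and muscle and stroma. Lists with 3 or more tested members were tested with camera in limma 3.58.1 at a preset correlation of 0.01 against the other miRNAs or features, and again with an estimated correlation. The fry test, whose p is unadjusted, asks whether the members of a list move one way on balance, without setting them against others. The endothelial list had too few tested members. The named miRNAs are the 10 most abundant per table, the 5 with the smallest unadjusted p in each direction where fewer than 5 passed, and the member of each list with the smallest p. Between the tables, the 5 largest calls per direction above 10 CPM are named. For all features the 3 most abundant of each main class were considered, and only some of these are named. Genes named outside this rule were chosen after their values were seen, as were the exact tests of single abundant features and of list scores.

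Alternatives were DESeq2 size factors, library size only, no low-count filter, at least 10 CPM in 5 libraries, DESeq2 1.42.0, voom with quality weights, an adjusted p of 0.1, both runs summed per animal, miRNAs scaled by all features, medians in place of means, totals without rRNA, fits with or without the animal as a block, and leaving out each library or animal in turn. Fits, list tests and class shares without Control 9, Control 11 and MSUS 14 were added after seeing the low tRNA shares of these libraries and their place on the first principal coordinate. Library size only and leaving out each library were added for the transcript lists after the data were seen. Replicates differed by more than sampling noise, with chi-square per degree of freedom from 9.46 to 62.7 over the 40 pairs within groups, and all libraries were kept as separate replicates.

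The tests were first checked on simulated counts drawn from the real means, library sizes and fitted dispersions, with a known set of features altered. In the table labelled with size selection, over 249 simulated miRNAs, 68.4% of 1.5-fold, 100% of 2-fold and 100% of 4-fold changes were recovered. In the table labelled without, over 228 miRNAs, the shares were 36.8%, 85% and 100%. Over all features they were 17.5%, 64.9% and 96.2% of 9690 features in the first table and 15.3%, 61.3% and 100% of 989 features in the other. The interaction test recovered 75%, 90% and 100% over 256 miRNAs, and the comparison between tables recovered 100% at each size over 256 miRNAs. For the latter the simulated counts held no spread between animals, which the fit without the animal as a block meets in the real data. This check therefore cannot give its power there. Between 1 and 5 unaltered features were called in each simulated fit. Many miRNAs were altered at once, 19, 19 and 16 of the 249 for the 1.5-fold, 2-fold and 4-fold changes, with 49 calls in all. This eases the adjustment, so the shares recovered need not hold where few miRNAs differ. Each fit was simulated in 1 draw. The list test called a list raised by 0.5 on the log2 scale in both tables (adjusted p = 1.49e-14 and 4.06e-10), and no other list. The simulated miRNAs were drawn independently of each other, so this check cannot show false list calls that arise from correlated members. Figures were drawn with matplotlib 3.10.9. Coordinates of piRNAs in the identifiers are of an unstated build and are not used here.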

Results

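Small RNA carried by cauda epididymosomes was measured in 5 Control and 5 MSUS males at 9 months of age. The design asks whether stress in early life alters the RNA, and the miRNAs in particular, that these vesicles carry in adulthood. Each library was read in both runs, so that each table holds 5 samples per group. Totals ran from 1872084 to 3647956 counts in the table labelled with size selection (exact permutation p = 0.667 for Control against MSUS) and from 215231 to 871461 in the table labelled without (exact permutation p = 0.595). Between 499 and 629 miRNAs were detected per library in the first table and between 429 and 609 in the other.

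The most abundant miRNAs of the vesicles were first compared in the table labelled with size selection. miR-148a-3p averaged 111296 ± 41535 CPM in Control and 115410 ± 27573 CPM in MSUS libraries (SD, n = 5 each), and miR-143-3p, a miRNA of smooth muscle and stroma, 98196 ± 17702 and 115751 ± 33987 CPM. The log2 fold changes of miR-10a-5p, miR-21a-5p, miR-26a-5p, miR-10b-5p and miR-99a-5p lay between −0.03 and +0.05. Those of miR-200b-3p (−0.22, SE 0.12), let-7f-5p (−0.16, SE 0.13) and miR-200c-3p (−0.18, SE 0.12) were negative, and that of miR-200b-3p turned to +0.29 when miRNAs were scaled by all features. let-7f-5p and miR-200c-3p also turned positive with that scaling, under which 10 of 10 let-7 and 9 of 9 epithelial miRNAs were positive. No miRNA passed the edgeR test (0 of 259 at an adjusted p of 0.05), with 7 at an unadjusted p under 0.05, 3 higher and 4 lower in MSUS (37 higher and 0 lower when scaled by all features), and 0 by DESeq2 or voom. Those 7 became 18 without Control 7 (10 higher and 8 lower), 18 without MSUS 14 (7 and 11), 14 without MSUS 8 (3 and 11), 5 without MSUS 6 (3 and 2) and 4 without MSUS 4 (1 and 3).

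Named next are the miRNAs with the smallest p, so that their counts of libraries beyond the Control mean, here and below, add no support. Over all tested miRNAs, all 5 values of a group lay beyond those of the other for 1 of 259 in this table (0.386%). In the table labelled without size selection this held for 0 of 233, where chance gives 0.794%. miR-155-5p, a regulator of immune cell activation, averaged 328 ± 46.4 CPM in Control and 229 ± 28.0 CPM in MSUS libraries (log2 −0.51, SE 0.17, adjusted p = 0.869), with 5 of 5 MSUS libraries below the Control mean. miR-31-5p averaged 1299 ± 238 and 926 ± 113 CPM (log2 −0.49, SE 0.16, adjusted p = 0.869, 5 of 5 below), and its log2 fold change became +0.02 when scaled by all features. miR-484 (133 ± 29.1 and 92.2 ± 28.4 CPM), miR-690 (371 ± 79.7 and 279 ± 59.8 CPM) and miR-744-5p (473 ± 109 and 367 ± 54.7 CPM) had lower MSUS means, and miR-690 (+0.20) and miR-744-5p (+0.18) turned positive when scaled by all features. miR-34c-5p, a miRNA of male germ cells, averaged 5739 ± 1268 CPM in Control and 8180 ± 2220 CPM in MSUS (log2 +0.51, SE 0.18, adjusted p = 0.980), with 4 of 5 MSUS libraries above the Control mean. The related miR-34b-5p stood at 65.0 ± 31.3 and 97.2 ± 20.1 CPM, and miR-878-5p and miR-470-5p of the X-linked cluster at 158 ± 30.8 and 219 ± 36.6 CPM and at 292 ± 39.4 and 371 ± 91.6 CPM, each higher in 5 of 5 MSUS libraries than the Control mean. miR-184-3p differed by +0.35 (SE 0.21). miR-31-5p is encoded on chromosome 4 (88910557 to 88910662, minus strand, within a lincRNA gene), miR-155-5p on chromosome 16 (84714140 to 84714204, within Mir155hg), miR-34c-5p on chromosome 9 (51103034 to 51103110, opposite to Btg4) and miR-878-5p on chromosome X (66801508 to 66801585), all in GRCm38.

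Of 233 miRNAs tested in the table labelled without size selection, 0 passed the edgeR test, with 13 at an unadjusted p under 0.05 (4 higher and 9 lower in MSUS, but 32 higher and 0 lower when scaled by all features) and 0 by DESeq2 or voom. These 13 became 29 without MSUS 14 (15 higher and 14 lower), 18 without Control 7 (10 and 8), 16 without Control 11 (8 and 8) and 7 without MSUS 4 (2 and 5). let-7a-5p, of a family that restrains growth and proliferation, averaged 10165 ± 695 CPM in Control and 7495 ± 1829 CPM in MSUS (log2 −0.44, SE 0.15, adjusted p = 0.498), with 5 of 5 MSUS libraries below the Control mean. let-7c-5p (16317 ± 2561 and 12219 ± 2282 CPM) and let-7d-5p (4222 ± 408 and 3218 ± 740 CPM) also lay below it in 5 of 5. miR-223-3p, a miRNA of myeloid cells encoded on chromosome X (96242817 to 96242926, plus strand), averaged 212 ± 40.3 and 137 ± 23.7 CPM (log2 −0.62, SE 0.21, adjusted p = 0.498, 5 of 5 below). miR-31-5p was at 1072 ± 348 and 715 ± 93.5 CPM (log2 −0.59, SE 0.21, adjusted p = 0.498, 5 of 5 below). On the higher side were miR-878-5p (154 ± 53.5 and 247 ± 47.3 CPM, log2 +0.68, SE 0.24, adjusted p = 0.498, 5 of 5 above) and miR-881-3p (1976 ± 691 and 2976 ± 829 CPM, log2 +0.60, SE 0.24, adjusted p = 0.771, 4 of 5 above). miR-381-3p was at 70.1 ± 32.0 and 119 ± 53.5 CPM, miR-34c-5p at 4024 ± 845 and 5278 ± 1428 CPM, and miR-465b-5p at 698 ± 107 and 887 ± 88.9 CPM. The same 10 miRNAs were the most abundant, with log2 fold changes from −0.28 (let-7f-5p, SE 0.12) to +0.28 (miR-143-3p, SE 0.18). miR-200b-3p (−0.11) and miR-200c-3p (−0.22) became +0.20 and +0.12 when scaled by all features. That scaling moved the median log2 fold change of all tested miRNAs to +0.53 in the first table and +0.33 in this one, against +0.03 and +0.00 with miRNA totals. It is not the share of all counts. By share, miRNA took 14.0% in Control and 12.7% in MSUS libraries of the first table, and 62.5 and 65.6% in this one. Over all features of the first table, miR-34c-5p was at +0.98 with TMM and +0.34 with library size only, so the reversals depend on how all features are scaled.

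**Figure D1:**
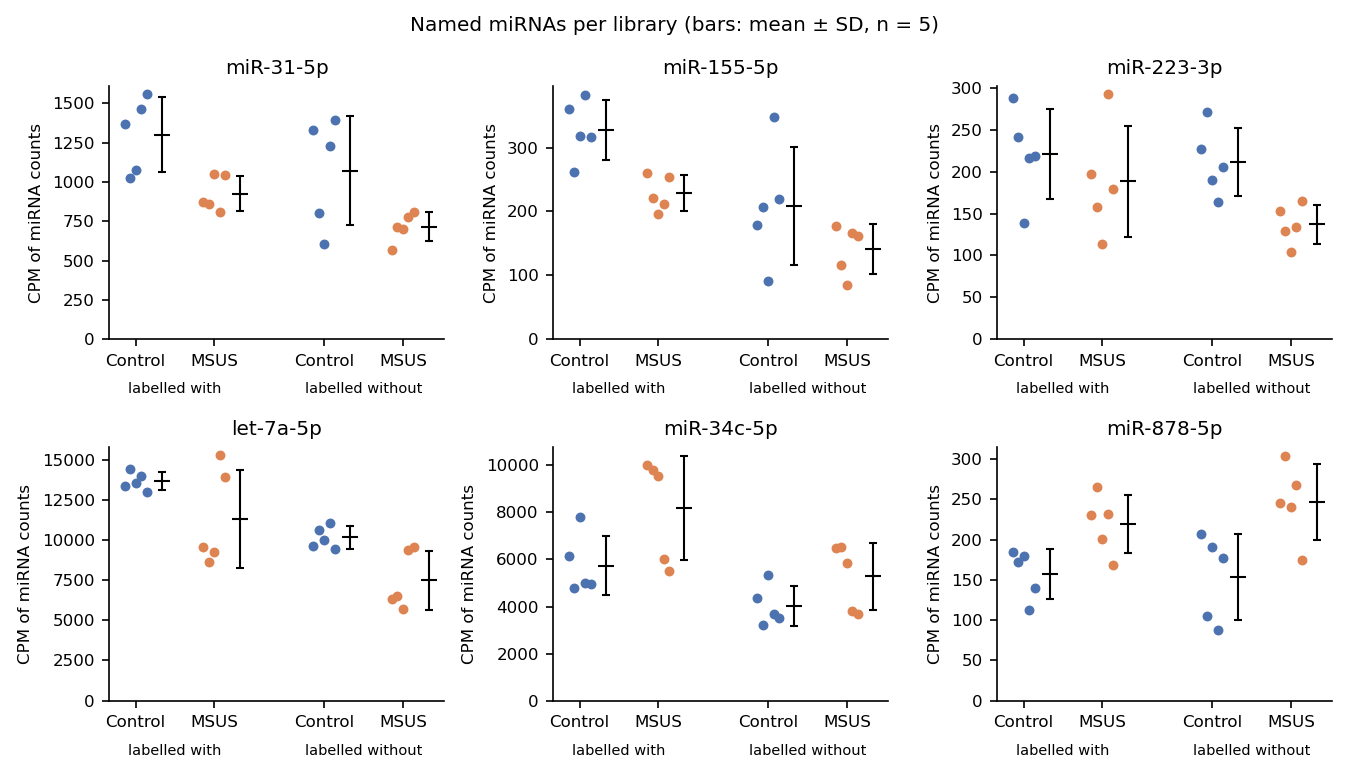
Level of 6 miRNAs in each library, in CPM relative to the miRNA total, for Control and MSUS males in the table labelled with and the table labelled without size selection; points are libraries and bars the mean ± SD (n = 5). In the table labelled with size selection miR-155-5p averaged 328 CPM in Control and 229 CPM in MSUS libraries and miR-34c-5p 5739 and 8180 CPM, and the lower MSUS values of miR-31-5p and let-7a-5p there turned positive (+0.02 and +0.30, log2) when miRNAs were scaled by all features.

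Groups of miRNAs were compared with all other miRNAs. The X-linked cluster of the male reproductive tract rose in MSUS in both tables by camera. It had 17 of 19 members positive in the table labelled with size selection (median log2 fold change +0.11, adjusted p = 0.0138) and 19 of 19 in the other (median +0.25, adjusted p = 3.64e-06). Neither call held with an estimated correlation (adjusted p = 0.394 and adjusted p = 0.156 with an estimated correlation; fry p = 0.143 and 0.0468). miR-881-3p differed by +0.46 (SE 0.30) in the first table, and miR-743b-5p by +0.70 (SE 0.38) in the second. By camera the let-7 family fell, with 8 of 10 members negative in the first table (median −0.15, camera adjusted p = 0.0138) and 9 of 10 in the other (median −0.26, camera adjusted p = 4.80e-06), though scaled by all features 10 of 10 and 7 of 10 were positive. These calls were lost, at adjusted p = 0.394 and adjusted p = 0.156 with an estimated correlation (fry p = 0.156 and 0.0273). Under that scaling 8 of 10 and 9 of 10 let-7 members still lay below the median of all miRNAs. As a score, the mean log2 CPM of the members in each library, let-7 hardly differed in the first table (−0.01, exact permutation p = 0.960). In the second its score differed by −0.27 (exact permutation p = 0.0556, adjusted p = 0.315). let-7a-5p differed by −0.27 (SE 0.15) in the first table, where let-7b-5p (−0.22), let-7c-5p (−0.20) and let-7d-5p (−0.23) were also negative and let-7j was at +0.27. Adjusted over the list alone, 2 let-7 members passed in the second table (let-7a-5p and let-7c-5p, adjusted p = 0.0383) and 0 in the first, against 0 over all miRNAs tested. For the X-linked cluster the counts adjusted over the list alone were 0 and 0.

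The call of the let-7 family in the first table ended without Control 5 (adjusted p = 0.0800), Control 7 (0.144), Control 9 (0.0715), MSUS 2 (0.0741), MSUS 4 (0.0658) or MSUS 6 (0.0589), and its median moved to −0.25 without MSUS 8. That of the X-linked cluster ended without Control 5 (0.0690) or Control 9 (0.212), and its median was +0.19 without Control 3, +0.19 without Control 11 and +0.16 without MSUS 14. In the second table both calls held without each library, and the X-linked median was +0.13 without Control 9, +0.16 without MSUS 2 and +0.39 without Control 11.

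The family of miR-34 and miR-449, typical of germ cells and of ciliated epithelia, rose in MSUS in the first table, with 5 of 6 members positive (median +0.20, camera adjusted p = 0.0138, fry p = 0.0795; adjusted p = 0.345 with an estimated correlation). miR-449a-5p differed by +0.24 and miR-34a-5p by −0.10. This call ended without Control 5 (0.151), MSUS 2 (0.0741) or MSUS 6 (0.0589), and the median was +0.34 without Control 11. In the second table its 6 members were all positive (median +0.13, adjusted p = 0.204), and the list passed without MSUS 8 (0.0386). miRNAs of blood cells fell in both tables, with 7 of 8 members negative in the first (median −0.23, camera adjusted p = 0.0138) and 6 of 7 in the second (median −0.36, camera adjusted p = 0.0449), though scaled by all features 7 of 9 and 3 of 7 were positive. These calls were lost, at adjusted p = 0.245 and adjusted p = 0.156 with an estimated correlation (fry p = 0.0377 and 0.0701). Of the 9 and 7 miRNAs scaled by all features, 8 and 6 still lay below the median of all miRNAs. In the first table miR-150-5p of lymphocytes differed by −0.47 (SE 0.26), miR-223-3p by −0.23 (SE 0.22) and miR-451a of red blood cells by −0.27 (SE 0.30), while miR-486a-5p was at +0.16 (SE 0.27) and miR-16-5p at −0.07. In the second, miR-155-5p was at −0.64 (SE 0.28), miR-150-5p at −0.39, miR-142a-5p at −0.36, miR-486a-5p at +0.25 and miR-16-5p at −0.01. The blood cell call in the first table ended without Control 3 (0.0658), Control 5 (0.0741) or Control 9 (0.116), with medians of −0.14 without Control 3, −0.35 without Control 11 and −0.38 without MSUS 8. In the second it ended without Control 3 (0.211), Control 5 (0.103), Control 9 (0.271), MSUS 4 (0.0983), MSUS 6 (0.134), MSUS 8 (0.190) or MSUS 14 (0.238), with medians of −0.11 without Control 3, −0.21 without Control 7, −0.19 without Control 9 and −0.12 without MSUS 14. Adjusted over the list alone, 0 members of either list passed in either table.

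Libraries Control 9, Control 11 and MSUS 14 stood apart by their low tRNA share in the first table, at 14.5, 25.3 and 23.8% against 34.6 to 66.0% in the other 7 libraries. They also held the most miRNA counts, 387343, 550396 and 492954 in the first table and 359201, 575372 and 505532 in the second. The highest of the other libraries had 332406 and 355639. Without these 3, the blood cell list no longer passed (adjusted p = 0.0604 and 0.385 in the tables labelled with and without size selection), and 3 and 2 miRNA lists passed in place of 4 and 3. Inflammation-related miRNAs, which share miR-155-5p and miR-223-3p with the blood cell list, were not called in the second table (7 of 9 negative, median −0.04, adjusted p = 0.0544, and 0.156 with an estimated correlation; fry p = 0.00424). They passed there without Control 9 (0.0471) or MSUS 8 (0.0386), and in the first table the adjusted p was 0.151 (6 of 10 negative). Adjusted over the list alone, 2 of its members passed in each table, miR-31-5p and miR-155-5p in the first (adjusted p = 0.0336) and miR-223-3p and miR-31-5p in the second (adjusted p = 0.0428), against 0 over all miRNAs tested.

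The other lists did not pass in either table, and adjusted over the list alone 0 of their members did. Adjusted p values in the first and second table were 0.693 and 0.436 for the miR-10/99/100 family, where miR-100-5p differed by +0.09 and +0.14. They were 0.504 and 0.911 for epithelial miRNAs and 0.584 and 0.771 for muscle and stroma miRNAs. For miRNAs of liver and neural tissue they were 0.258 and 0.197, with miR-9-5p at +0.26 (SE 0.18) and +0.48 (SE 0.25). The miR-17/92 clusters gave 0.693 and 0.385, with miR-19a-3p at +0.35 (SE 0.23) in the first table and miR-20a-5p at −0.24 (SE 0.25) in the second, which became +0.04 when scaled by all features. The miR-29 and miR-30 families gave 0.504 and 0.314, with miR-30e-5p at +0.23 (SE 0.17) and miR-30e-3p at +0.29 (SE 0.17). The Dlk1-Dio3 cluster gave 0.679 and 0.120, with miR-381-3p at +0.65 (SE 0.54) and +0.81 (SE 0.37). The Sfmbt2 cluster gave 0.679 and 0.771, and in the second table its test and mean (−0.03) were negative and its median +0.00. Its member with the smallest p was miR-466a-3p (+0.36, SE 0.29) in the first table and miR-467a-5p (−0.45, SE 0.28) in the second, each counted together with other miRNAs of the same sequence. Sperm miRNAs of an earlier study of paternal stress gave 0.781 and 0.314, with miR-30a-5p at +0.07 (SE 0.14) in the first table, which was −0.04 without Control 11, and miR-204-5p at +0.33 (SE 0.25) in the second. Those of an earlier MSUS study gave 0.693 and 0.485, with a negative test and mean (−0.03) and a positive median (+0.06) in the first table.

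**Figure D2:**
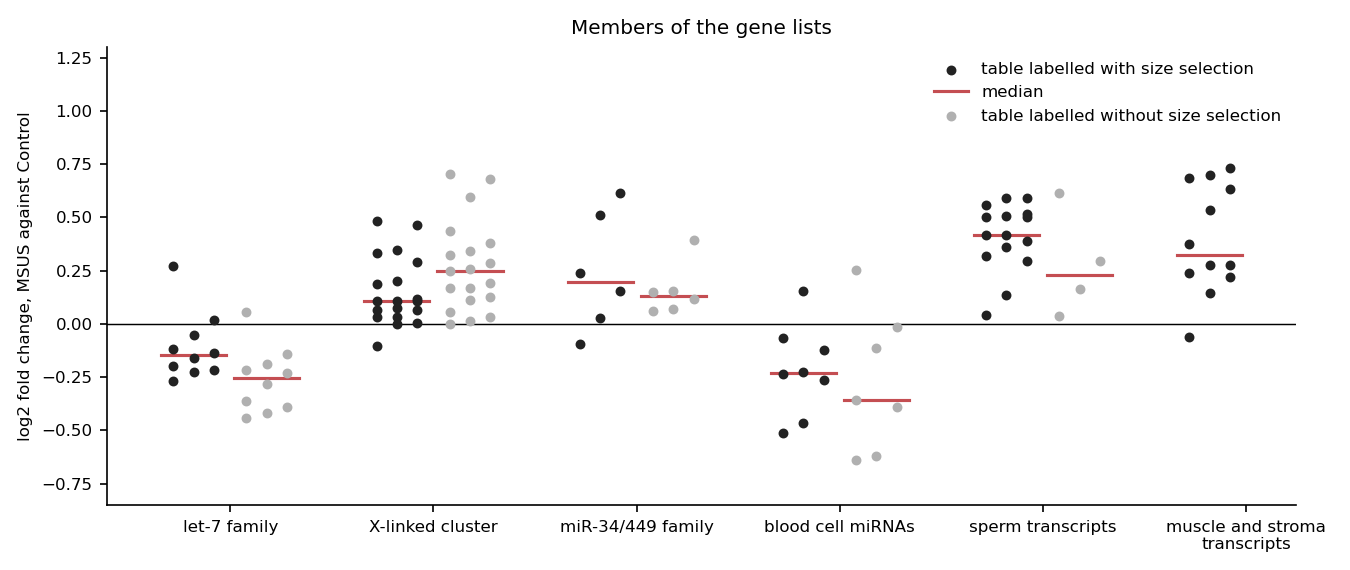
Log2 fold change of each member, MSUS against Control, for 4 miRNA lists and 2 transcript lists; each point is a miRNA or transcript of the table labelled with (dark) or without (light) size selection, and red lines are medians. Positive values in the first table were those of 17 of 19 X-linked miRNAs and 15 of 15 sperm transcripts, and negative those of 8 of 10 let-7 and 7 of 8 blood cell miRNAs, but let-7 and most blood cell miRNAs there turned positive when scaled by all features, and sperm and most muscle transcripts negative with library size only.

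All annotated RNAs were compared in the same way. Transcripts of sperm and spermatids rose in MSUS in the table labelled with size selection, with 15 of 15 members positive (median log2 fold change +0.42, camera adjusted p = 3.20e-10), though 0 of 15 with library size only. This call was lost, at adjusted p = 0.118 with an estimated correlation (fry p = 0.0581). Smcp, a protein of the sperm mitochondrial capsule (chromosome 3, 92583867 to 92588997), differed by +0.59 (SE 0.14, adjusted p = 0.839), Odf1 of the sperm tail by +0.59 (SE 0.17), Ldhc by +0.51 (SE 0.21), Prm2 by +0.56 (SE 0.25) and Prm1 by +0.14 (SE 0.31). Adjusted over the list alone, 2 of them passed, Smcp (adjusted p = 0.0104) and Odf1 (adjusted p = 0.0251), against 0 over all features tested. Transcripts of muscle and stroma also rose, with 11 of 12 members positive (median +0.32, camera adjusted p = 2.88e-05), and 5 of 12 with library size only. This call was lost, at adjusted p = 0.118 with an estimated correlation (fry p = 0.0596). The smooth muscle genes Myh11 (+0.68, SE 0.30), Actg2 (+0.73, SE 0.35), Tagln (+0.63, SE 0.31) and Acta2 (+0.54, SE 0.29) were among them, and Col1a2 was at −0.06. Without Control 9, Control 11 and MSUS 14, both lists still passed, with medians of +0.59 and +0.31, and the blood cell transcripts did too (adjusted p = 0.0398, 3 tested). With library size only, 15 of 15 sperm and 11 of 12 muscle and stroma transcripts still lay above the median of all features, which that scaling moved to −0.58, and to −0.30 in the other table.

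The 3 blood cell transcripts tested were Lyz2 (+0.39, SE 0.22), S100a8 (+0.20, SE 0.32) and Cd74 (+0.07, SE 0.17), with an adjusted p of 0.141 for the list, which passed without Control 5 (0.0432) or Control 9 (0.0263). Each of them was negative with library size only. Transcripts of epididymal epithelium gave an adjusted p of 0.940, with 8 of 16 members positive, a negative test, a median of +0.02 and a mean of +0.04, and 0.0432 without Control 5. Its members included the sperm-coating protein gene Crisp1 (−0.04, SE 0.21), the water channel gene Aqp9 (−0.32, SE 0.11) and Gpx5 (+0.46, SE 0.27, negative with library size only). Of 9 epididymal transcripts in the table labelled without size selection, 8 were negative (median −0.20, adjusted p = 0.0525), among them Aqp9 (−0.49, SE 0.25) and Spink8 (−0.39, SE 0.24). That list passed without Control 5 (0.0219), MSUS 2 (0.0347) or MSUS 14 (0.00884). All 4 sperm transcripts there were positive (median +0.23, adjusted p = 0.166), with Odf1 at +0.61 (SE 0.30), and 2 of 4 with library size only. Adjusted over the list alone, 0 members of these other transcript lists passed, and too few blood cell and muscle transcripts were tested in this table.

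Per feature, 0 of 10998 features passed in the table labelled with size selection by edgeR, with 635 at an unadjusted p under 0.05 (380 higher and 255 lower in MSUS, but 3 and 2323 with library size only), 33 calls by DESeq2 (32 higher and 1 lower), which gave 10448 features no adjusted p, and 0 by voom. Without the low-count filter edgeR called 48 there, 40 higher and 8 lower. Of 1075 features in the other, 0 passed, with 85 at an unadjusted p under 0.05 (38 higher and 47 lower) and 0 by DESeq2 or voom. Directions at an unadjusted p under 0.05 depended on the setting there. Library size only gave 4 higher and 178 lower. The counts were 60 higher and 39 lower by DESeq2, 75 and 69 by voom and 134 and 83 at 10 CPM in 5 libraries. Without MSUS 14 there were 154, 94 higher and 60 lower, and the higher features were also the more numerous without Control 5 (54 and 48), Control 7 (42 and 34) or MSUS 2 (35 and 33). All 5 values of a group lay beyond those of the other for 95 of 10998 features (0.864%) and 15 of 1075 (1.40%), where chance gives 0.794%. Without Control 3, 2 transcripts passed in the first table, both of Mfsd2a, a lipid transporter gene chosen after its values were seen (−1.24 and −1.31, adjusted p = 0.0182 and 0.00692). With library size only, 3 features passed there, the same Mfsd2a transcripts (−1.67 and −1.72) and Prdm10 (−1.80), each at adjusted p = 0.0439, and 1 in the other table, Larp1 (−1.51, adjusted p = 0.0480), all chosen after their values were seen.

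Shares of the most abundant RNAs were set beside these fits, in tests chosen after the values were seen. Akr1b7, an aldo-keto reductase and the most abundant protein-coding transcript (chromosome 6, 34412334 to 34423142), made up 1.88 ± 0.320% of counts in Control and 0.909 ± 0.219% in MSUS libraries of the table labelled with size selection (SD, n = 5 each). In the other table it made up 0.443 ± 0.0572 and 0.244 ± 0.0740%. Each MSUS value lay below each Control value in both tables (exact permutation p = 0.00794, the smallest possible; adjusted p = 0.0754 and 0.151 over 38 features). Gm43305, a noncoding RNA on chromosome 14 (54292443 to 54297456), stood at 0.355 ± 0.00888 and 0.207 ± 0.0624%, and at 0.269 ± 0.0321 and 0.174 ± 0.0310%, with the same p values. With TMM scaling, edgeR gave Akr1b7 a log2 fold change of −0.41 (SE 0.28, adjusted p = 0.895) in the first table and −0.63 (SE 0.25, adjusted p = 0.554) in the other. Gm43305 was at −0.18 (SE 0.23, adjusted p = 0.979) and −0.39 (SE 0.19, adjusted p = 0.554) by the same fits. Crisp1 made up 0.259 ± 0.0965 and 0.169 ± 0.0769% in the first table. tRNA Gly was the most abundant RNA, at 24.5 ± 9.28% in Control and 34.5 ± 11.7% in MSUS (exact permutation p = 0.198, adjusted p = 0.838, 4 of 5 MSUS libraries above the Control mean), and tRNA Glu was at 4.47 ± 1.77 and 6.81 ± 2.53%. In the other table tRNA Gly took 10.1 ± 5.14 and 9.88 ± 2.29%, a log2 fold change of +0.19 (SE 0.34) with TMM that became −0.06 with library size only. The most abundant of the remaining classes in the first table were the piRNA mmu_piR_000935 (0.644 ± 0.214 and 0.733 ± 0.258%), the rRNA n-R5-8s1 (0.930 ± 0.458 and 0.891 ± 0.331%), mt-Rnr2 (0.766 ± 0.151 and 0.757 ± 0.185%), mt-Th (0.594 ± 0.238 and 0.722 ± 0.361%), the Y RNA Rny1 (0.705 ± 0.112 and 0.650 ± 0.198%), Snord83b (0.171 ± 0.0451 and 0.174 ± 0.0788%) and Gas5 (0.649 ± 0.282 and 0.559 ± 0.288%). The snRNA Gm22513 stood at 0.691 ± 0.159 and 0.672 ± 0.251%, and the miRNA precursor class was led by Snord43 (0.0566 ± 0.0313 and 0.0520 ± 0.0233%). Its members AC099934.1 and AC157822.1 had identical values (0.0282 ± 0.00491 and 0.0168 ± 0.00330%, exact permutation p = 0.00794, adjusted p = 0.0754). With TMM scaling AC099934.1 was at −0.09 (SE 0.28).

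**Figure D3:**
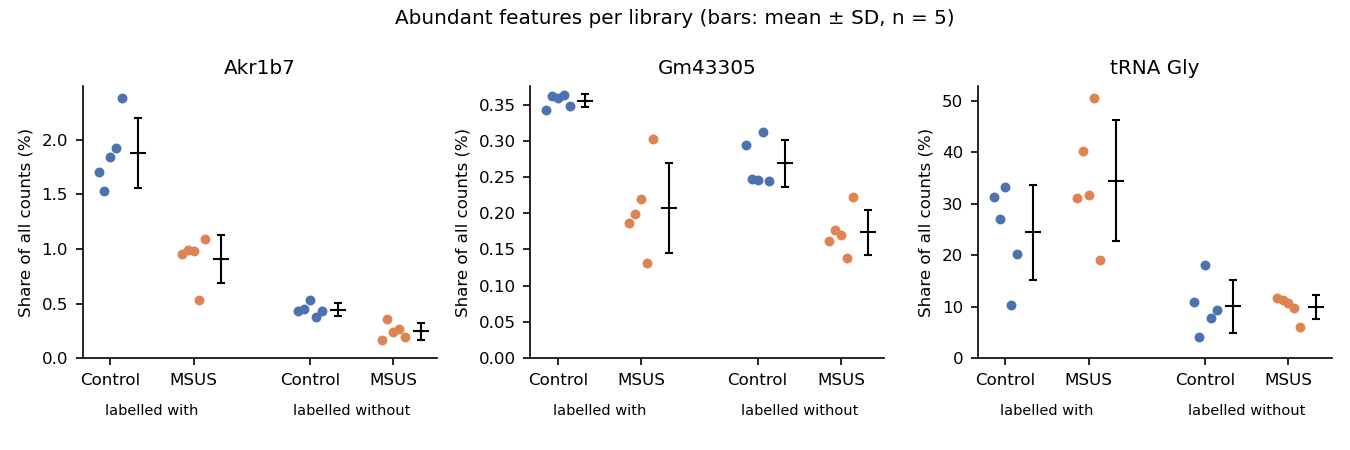
Share of all counts (%) of Akr1b7, Gm43305 and tRNA Gly in each library of Control and MSUS males, in the table labelled with and the table labelled without size selection; points are libraries and bars the mean ± SD (n = 5). Akr1b7 averaged 1.88% in Control and 0.909% in MSUS libraries of the table labelled with size selection, and tRNA Gly 24.5 and 34.5%.

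By RNA class, tRNA made up 31.2 ± 11.5% of counts in Control and 44.5 ± 15.5% in MSUS libraries of the table labelled with size selection (SD, n = 5 each; exact permutation p = 0.159), miRNA 14.0 ± 2.47 and 12.7 ± 2.45% (exact permutation p = 0.468) and protein-coding transcripts 23.7 ± 5.02 and 15.4 ± 6.42% (exact permutation p = 0.0556). The lncRNA share was 1.18 ± 0.182% in Control and 0.800 ± 0.177% in MSUS (exact permutation p = 0.00794, adjusted p = 0.127). No class passed the adjustment over 16 classes (0 of 16), with 1 at an unadjusted p under 0.05. Without MSUS 14, 3 classes passed (adjusted p = 0.0423 each), with differences of MSUS minus Control of −10.7% for protein-coding transcripts, −0.440% for lncRNA and −0.328% for misc_RNA. In the table labelled without size selection, 0 of 16 classes passed and 4 had an unadjusted p under 0.05. Protein-coding transcripts made up 10.5 ± 1.73% in Control and 7.48 ± 1.40% in MSUS (exact permutation p = 0.0159, adjusted p = 0.0952). miRNA precursors (0.0902 ± 0.0178 and 0.0601 ± 0.0125%), lncRNA (0.992 ± 0.195 and 0.781 ± 0.0794%) and pseudogenes (0.538 ± 0.0706 and 0.418 ± 0.0593%) had the same adjusted p. miRNA stood at 62.5 ± 7.82 and 65.6 ± 4.13%, and tRNA at 14.1 ± 6.97 and 14.4 ± 3.34%.

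The 2 runs were then compared with each other. Size selection cannot be told apart here from the run or from depth. Totals in the table labelled with size selection were 3.65 (MSUS 6) to 13.8 times (MSUS 2) those of the other. The labels also conflict with the contents, so the differences below are between tables and are not assigned to size selection. miRNA made up 13.4 ± 2.43% of counts in the table labelled with size selection and 64.0 ± 6.12% in the table labelled without (SD, n = 10), and was higher in the latter in 10 of 10 animals, which is against the labels. The table labelled with size selection held more tRNA (37.8 ± 14.6% against 14.3 ± 5.15%), snRNA (11.3 ± 3.56% against 1.80 ± 0.651%), snoRNA (3.94 ± 1.67% against 0.954 ± 0.329%) and protein-coding transcripts (19.6 ± 6.98% against 9.00 ± 2.19%), each in 10 of 10 animals, and less piRNA (1.27 ± 0.220% against 1.66 ± 0.182%, lower in 10 of 10). Each of these had an exact sign-flip p of 0.00195, the smallest possible (adjusted p = 0.00284). The tRNA share rested largely on tRNA Gly, at 29.5% of counts in the table labelled with size selection against 9.97%. The piRNA mmu_piR_000935 went against its class, at 0.688% there against 0.258%. Of 16 classes, 15 passed; misc_RNA did not (adjusted p = 0.0879), and rRNA (adjusted p = 0.0424, higher in the table labelled without in 8 of 10 animals) and lncRNA (adjusted p = 0.0458) were near the threshold.

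**Figure D4:**
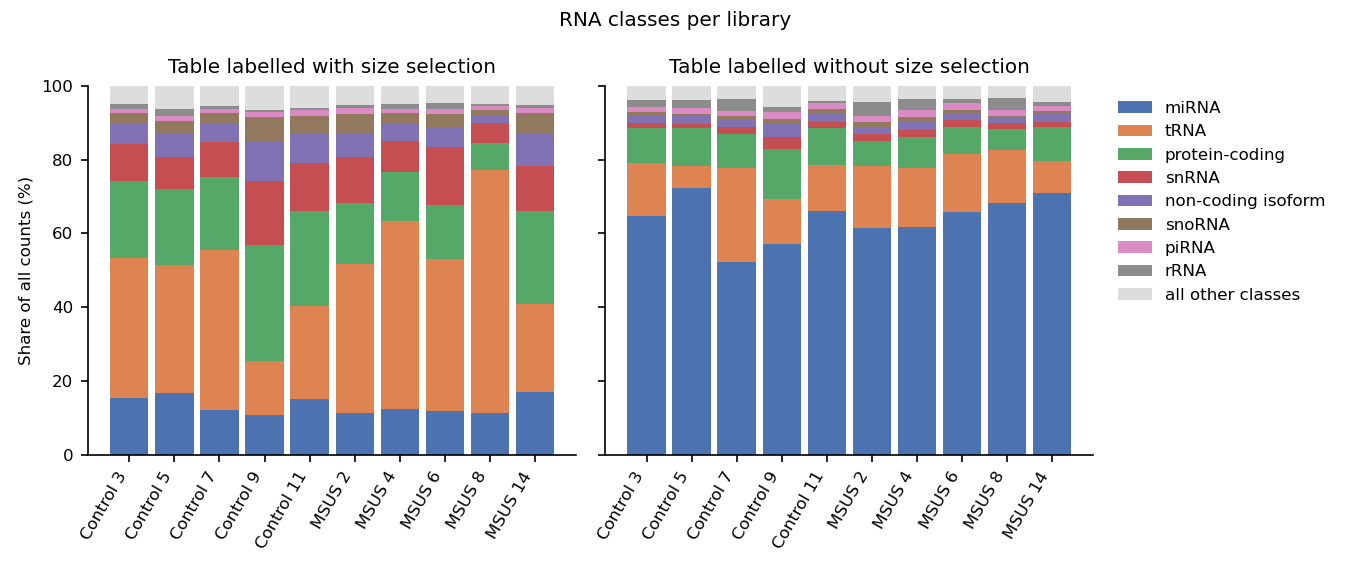
Share of all counts (%) of 8 RNA classes and of all others, one bar per library, in the table labelled with (left) and the table labelled without (right) size selection. miRNA averaged 13.4% in the first and 64.0% in the second, and tRNA 37.8 and 14.3%.

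Feature by feature, 2217 of 5725 RNAs differed between the tables by edgeR, 1140 higher and 1077 lower in the table labelled with size selection. All 265 miRNAs were lower there (median log2 fold change −3.15), among them miR-125b-5p (−4.13, SE 0.21), miR-296-5p (−4.03, SE 0.30) and miR-374b-5p (−3.92, SE 0.26), as were the 5S rRNA genes n-R5s5 (−4.01, SE 0.49) and n-R5s151 (−3.91, SE 0.53), whose copies share reads. The snoRNAs Snord2 (+4.34, SE 0.34), which guides modification of rRNA from within Eif4a2 (chromosome 16, 23108953 to 23109021), Gm23650 (+4.23, SE 0.47), Gm22357 (+4.02, SE 0.44) and Snord95 (+3.94, SE 0.27) were the most raised, with a retained intron transcript of Eif4a2 (+3.95, SE 0.30). Of 175 snoRNAs 85 were higher and 44 lower, of 43 piRNAs 0 and 31, of 22 tRNAs 1 and 13, and of 4182 protein-coding transcripts 758 and 514. Of 84 snRNAs 29 were higher and 40 lower, against 43 and 27 with library size only. With the animal as a block 2430 RNAs were called, 1240 higher and 1190 lower, among them 94 and 51 snoRNAs, 1 and 38 piRNAs, 6 and 14 tRNAs, 826 and 592 protein-coding transcripts and 32 and 42 snRNAs. Of 17 mitochondrial tRNAs 7 and 6 were called with it and 4 and 3 without, and of 2 mitochondrial rRNAs 2 were lower with it and 0 without. Library size only called 4632 features, 4211 higher and 421 lower, as it moved the median of all features from +0.06 to +1.06. With it 8 tRNAs were higher and 13 lower, 125 and 20 snoRNAs, 2 and 21 piRNAs, and 3307 and 15 protein-coding transcripts. The 265 miRNAs were lower under it too.

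Within the miRNAs, 55 of 256 differed between the tables relative to the others, 36 higher and 19 lower in the table labelled with size selection, and 147 did with the animal as a block (72 higher and 75 lower). The let-7 family was higher there for 9 of 10 members (median log2 fold change +0.45), led by let-7b-5p (+0.79, SE 0.10). miR-3970 (+1.32, SE 0.20), miR-3535 (+1.07, SE 0.25), miR-135a-5p (+0.98, SE 0.15) and miR-669a-5p, which shares its sequence with miR-669p-5p (+0.81, SE 0.28), were also higher. miR-125b-5p (−0.93, SE 0.22), miR-296-5p (−0.82, SE 0.26), miR-374b-5p (−0.76, SE 0.20), miR-322-3p (−0.69, SE 0.23) and miR-326-3p (−0.63, SE 0.20) were lower. Of the miR-17/92 clusters 3 of 9 members were higher and of the miR-34 and miR-449 family 2 of 6. With the block these counts were 5 higher and 1 lower, and 4 higher and 2 lower. None of the 9 epithelial miRNAs, of the 10 muscle and stroma miRNAs or of the 10 miR-29 and miR-30 miRNAs was called without the block (0), and 4, 8 and 4 were with it.

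The MSUS effect itself was compared between the tables over the same animals. The log2 fold changes of 231 miRNAs had the same sign in both for 177 (76.6%), with a correlation across miRNAs, which are not independent replicates, of 0.697 (Spearman 0.654). With at least 10 CPM in 5 libraries of both runs the correlation was 0.433 over 337 miRNAs. The interaction of run and condition called 0 of 279 miRNAs by edgeR, with 23 at an unadjusted p under 0.05 (2 higher and 21 lower in the table labelled with size selection). With DESeq2 size factors there were 12 (8 higher and 4 lower), and without the animal as a block 0, so that the direction of these miRNAs depended on the scaling. Because both tables come from 1 set of libraries, a direction found in both is not found in separate animals.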

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

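The tests of the size selection and of the table names were chosen after the class shares had been seen.

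In the table labelled with size selection, MSUS 14 lay far above the other MSUS libraries in its miRNA share, at 17.0% of counts against 11.2 to 12.3%. Its level of miR-484 was 141 CPM, against 67.3 to 87.1 CPM in the other MSUS libraries. Control 9 lay far above the other Control libraries in its share of miRNA precursors (0.190% against 0.117 to 0.135%) and of lncRNA (1.5% against 1.04 to 1.15%). In the table labelled without size selection, Control 9 was again the highest Control library for protein-coding transcripts (13.6% against 9.40 to 10.1%), non-coding isoforms of coding genes (3.46% against 2.13 to 2.44%) and lncRNA (1.34% against 0.871 to 0.937%). Such gaps were found in 7 of 148 groups of 5 libraries (4.73%), and chance gives about 1 in 20.

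The share of miRNA went against the labels of the tables. Selection for miRNAs in the table so labelled would raise the miRNA share there, and 0 of 10 animals had the higher share in that table, which argues against the labels as given. Interchanged table names are a candidate explanation that stays open: with miRNA left out of the totals, the table labelled without size selection held less snRNA and more piRNA in 10 of 10 animals, but less tRNA in only 6 of 10. The sample labels also leave the order of the runs unclear, as what read as dates in their descriptions put the run numbered 2 before the run numbered 1, and selection of a different size range was not tested. No biological explanation was tested, since both runs read the same libraries.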

How the results depend on the processing

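The tests without Control 9, Control 11 and MSUS 14, and for the transcript lists those with library size only and without each library in turn, were chosen after the result was seen.

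Of 2359 alternative values for 178 results, 2176 kept their direction and their side of the threshold or moved little, 50 were no longer past the threshold, 16 newly passed it, 95 reversed and 22 counts or summary values moved. The cause was not tested unless stated. DESeq2 size factors, voom, a minimum of 10 CPM within a comparison and both runs summed per animal moved no count of calls at an adjusted p of 0.05 by over 1.5 times. Counts at an unadjusted p under 0.05 did move. The interaction had 23 miRNAs as reported (2 higher and 21 lower), 12 with DESeq2 size factors (8 and 4) and 0 without the block. All features in the table labelled without size selection had 38 higher and 47 lower as reported, 75 and 69 by voom and 134 and 83 at 10 CPM. For miRNAs the reported 7 and 13 in the tables labelled with and without size selection became 38 (24 higher and 14 lower) and 35 (19 and 16) without the low-count filter, which tested more miRNAs, and the 7 became 11 by voom (3 and 8) or at 10 CPM (6 and 5). With DESeq2 size factors some members near 0 changed sign, so that 3 of 5 of miR-10/99/100 in the first table were positive in place of 5. The feature at an adjusted p of 0.1 in the table labelled without size selection was lost under DESeq2 size factors, DESeq2, voom or 10 CPM (0 each). Fewer features could be tested in the table labelled without size selection (1075 against 10998), which had both lower totals and a higher miRNA share, and these were not told apart. With the animal as a block, 147 miRNAs in place of 55 differed between the tables, and 2430 features in place of 2217, with added calls in several classes and lists. The 20 features and miRNAs named for their fold change between the tables kept their calls with the block, and beyond these counts it changed no other call. Without the block, 14 of 16 classes in place of 15 differed between the tables, and the interaction again called 0 miRNAs. Counts over all features in the table labelled with size selection (0 as reported) became 3 with library size only, 48 without the low-count filter (40 higher and 8 lower) and 33 by DESeq2, which gave 10448 of 10998 features no adjusted p. In the other table they became 1 with library size only and 1 at an adjusted p of 0.1 (Larp1 in both), and 2 without Control 9, Control 11 and MSUS 14 (tRNA Asn, +1.63, and mt-Th, +1.53, chosen after their values were seen). Comparing the tables with library size only called 4632 features, which shifted the median of all features, and the agreement of fold changes between the runs was 0.433 at 10 CPM in 5 libraries of both runs. Scaled by all features, which raised the median of the tested miRNAs, log2 fold changes reversed to +0.020 for miR-31-5p, +0.20 for miR-690, +0.18 for miR-744-5p, +0.30 for let-7a-5p and +0.29 for miR-200b-3p in the table labelled with size selection, and to +0.12 for miR-200c-3p, +0.043 for miR-20a-5p and +0.20 for miR-200b-3p in the other. let-7f-5p and miR-200c-3p, not among these results, also turned positive with that scaling in the table labelled with size selection (10 of 10 let-7 and 9 of 9 epithelial miRNAs positive). With an estimated correlation 0 lists passed, neither miRNA lists in either table (0 and 0) nor transcript lists in the first (0). The adjusted p values were then 0.394 for the let-7 family and the X-linked cluster, 0.345 for the miR-34 and miR-449 family, 0.245 for blood cell miRNAs and 0.118 for sperm and for muscle transcripts in the first table, and 0.156 for let-7, the X-linked cluster and blood cell miRNAs in the second. Without Control 9, Control 11 and MSUS 14, that is with fewer samples, blood cell miRNAs had adjusted p values of 0.0604 and 0.385. Lists that were not called reversed there to adjusted p values of 0.769 (muscle and stroma miRNAs, and miRNAs of the earlier MSUS study) and 0.171 (epididymal transcripts, 0.814 with library size only) in the first table, and of 0.787 (epithelial), 0.525 (muscle and stroma), 0.513 (Sfmbt2 cluster) and 0.823 (earlier MSUS study) in the second. Differences in class shares, MSUS minus Control in percentage points, reversed without these 3 libraries to 1.16 for snRNA, 0.251 for snoRNA and −0.000204 for circRNA in the first table, and to 0.177 for mitochondrial rRNA and 0.487 for snRNA in the second. As differences of medians they reversed to 0.0403 for rRNA, 2.40 for snRNA and 0.198 for snoRNA in the first table, and to 0.394 for snRNA and 0.0892 for misc_RNA in the second.

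Leaving out 1 library in turn gave the following ranges in the table labelled with size selection: 0 (without Control 5) to 2 (without Control 3) features called, 0 to 4 miRNA lists (0 without Control 5, 1 without Control 9, 2 without MSUS 2 and 2 without MSUS 6), 2 to 4 transcript lists (4 without Control 5) and 0 to 3 classes (3 without MSUS 14). The log2 fold change of miR-30a-5p ran from −0.035 to +0.14. Adjusted p values ran from 0.000901 to 0.144 for let-7, 0.00197 to 0.151 for the miR-34 and miR-449 family, 0.000219 to 0.212 for the X-linked cluster and 0.000766 to 0.116 for blood cell miRNAs. For the lists not called they ran from 0.477 to 0.995 for miR-10/99/100, 0.148 to 0.950 for muscle and stroma miRNAs, 0.223 to 0.995 for miR-17/92, 0.0960 to 0.985 for Dlk1-Dio3, 0.355 to 0.985 for Sfmbt2, 0.607 to 0.999 for the earlier paternal stress study, 0.304 to 0.960 for the earlier MSUS study and 0.0432 (without Control 5) to 0.989 for epididymal transcripts. The other table had 0 to 1 transcript lists passing (1 without Control 5, MSUS 2 or MSUS 14), and adjusted p values ran from 0.0152 (without Control 7) to 0.271 for blood cell miRNAs, 0.692 to 0.983 for epithelial miRNAs, 0.317 to 0.944 for muscle and stroma miRNAs, 0.346 to 0.970 for Sfmbt2 and 0.206 to 0.970 for the earlier MSUS study. Class differences in percentage points ran from −0.176 to 0.142 for rRNA, −0.0398 to 0.0927 for mitochondrial rRNA, −0.0342 to 0.262 for mitochondrial tRNA, −1.92 to 0.670 for snRNA, −0.924 to 0.225 for snoRNA and −9.28e-05 to 0.000235 for circRNA in the first table. In the second they ran from −1.73 to 3.05 for tRNA, −0.0993 to 0.101 for mitochondrial rRNA, −0.260 to 0.288 for snRNA, −0.0780 to 0.165 for snoRNA and −0.290 to 0.0248 for misc_RNA. Control 9 was the library behind the highest value for snRNA in both tables, for snoRNA in both and for mitochondrial rRNA in the second.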

Other observations

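The tests of the divisions of Control and MSUS libraries, of their counts at an unadjusted p, of blood cells and of the 3 libraries left out were chosen after the result was seen, while those of the sperm scores, the interaction calls and the exchanges between tables were chosen before.

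By DESeq2, 33 features passed in the table labelled with size selection, 32 higher and 1 lower in MSUS, where edgeR called 0 with 635 at an unadjusted p under 0.05 and voom 0. DESeq2 gave no adjusted p to 10448 of the 10998 features, so that its adjustment ran over far fewer than that of edgeR. The largest class among the 33 was snRNA (14), many of them with values identical to those of the U1 genes Rnu1a1 (log2 +0.62, SE 0.20, DESeq2 adjusted p = 0.0362) and Rnu1b1 (+0.64, SE 0.20), each above the Control mean in 5 of 5 MSUS libraries in CPM of all features with TMM, the scale of all such counts here. Of snoRNAs there were 8, among them Snord95 (+0.95, SE 0.28), Snord83b (+0.58, SE 0.17) and Gm23246 (+0.85, SE 0.22), all higher in 5 of 5. The tRNAs His (+1.57, SE 0.48), Ala (+1.22, SE 0.38) and Thr (+1.08, SE 0.34) were higher in 4 of 5, and miR-34c-5p (+0.98, SE 0.29, DESeq2 adjusted p = 0.0362), mmu_piR_000935 (+0.82, SE 0.20, DESeq2 adjusted p = 0.0112) and Smcp (+0.59, SE 0.13, DESeq2 adjusted p = 0.00415) in 5 of 5. Relative to miRNA totals miR-34c-5p was higher in 4 of 5, and as a share of all counts mmu_piR_000935 was lower than the Control mean in 2 of 5. Hpgd, which degrades prostaglandins, was lower in 5 of 5 (−0.34, SE 0.09, DESeq2 adjusted p = 0.0206). With library size only, 12 of the 33 were positive and 21 negative, the 14 snRNAs and Smcp (−0.03) among the negative, and 32 of 33 lay above the median of all features. These features were named after their values were seen.

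Single MSUS libraries differed from each other in let-7a-5p and miR-34c-5p. Levels of let-7a-5p in the table labelled with size selection stood at 9549, 8653, 9250, 15290 and 13921 CPM in MSUS 2, 4, 6, 8 and 14, and at 12977 to 14413 CPM in the Control libraries. miR-34c-5p stood at 9995, 9812, 9568, 6016 and 5508 CPM in the same MSUS libraries, and at 4777 to 7787 CPM in Control. No test was made on these values.

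Sperm transcripts, the X-linked cluster and the miR-34 and miR-449 family were higher in MSUS libraries of the table labelled with size selection (Smcp 133 and 201 CPM, Odf1 60.1 and 91.1 CPM in Control and MSUS), as were 11 of 12 muscle and stroma transcripts (median +0.32) and 3 of 3 blood cell transcripts, but with library size only 0 of 15 sperm, 5 of 12 muscle and 0 of 3 blood cell transcripts were, though 15, 11 and 3 still lay above the median of all features. The libraries Control 9, Control 11 and MSUS 14 do not account for it, as the sperm transcript median was +0.59 without them. Sperm or spermatid RNA left in the pellet after swim-up and clearing spins is a candidate explanation: with condition means removed, the sperm transcript score correlated over 10 libraries with the X-linked score at 0.562 (permutation p = 0.0922, adjusted p = 0.461, 0.738 without Control 9 and MSUS 8) and with the miR-34 and miR-449 score at −0.192 (p = 0.602, adjusted p = 0.753, 0.439 without the same libraries). The negative value lay on the side set beforehand against sperm RNA, but within its spread and with its sign resting on 2 libraries, so neither relation decides, and over all libraries Pearson correlations were 0.695 (p = 0.0208, adjusted p = 0.104 over 5 relations, Spearman 0.648, p = 0.0487, and 0.663 without the same libraries) and 0.242 (p = 0.497, Spearman 0.261, p = 0.470, and 0.270 without them). A difference in the vesicles of MSUS males stays open too, untested. Levels of the X-linked cluster in sperm and in epididymis were not compared here, so its members cannot be used to tell these sources apart.

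Blood cell miRNAs were lower in MSUS libraries of both tables with miRNA totals (calls lost at adjusted p = 0.245 and adjusted p = 0.156 with an estimated correlation), but scaled by all features 7 of 9 were positive in the first and 3 of 7, with a median of −0.06, in the second, though 8 of 9 and 6 of 7 still lay below the median of all miRNAs. Less blood in the MSUS pellets may be the source, although spins before ultracentrifugation would remove whole cells. The red blood cell miRNAs miR-451a, miR-486a-5p and miR-16-5p, the last of which many tissues express, had a median log2 fold change of −0.068 (−0.27 to +0.16) at levels of 66.3, 557 and 1652 CPM in the table labelled with size selection, and members that go both ways decide nothing. The 5 white blood cell miRNAs, with miR-150-5p the most abundant at 1008 CPM, had a median of −0.24 (−0.51 to −0.12). The blood cell transcripts Lyz2 (+0.39), S100a8 (+0.20) and Cd74 (+0.07) were positive with TMM and negative with library size only. Under both, 3 of 3 lay above the median of all features. These transcripts need not come from the same white blood cells as the miRNAs. As the list holds only 3 tested transcripts and was not called (adjusted p = 0.141), less white blood cell RNA also stays open. Of 16 listed blood cell miRNAs 8 were tested here and 2 were also on another list, and a change in the MSUS vesicles themselves was not tested.

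Other divisions of the 10 libraries into groups of 5 were fitted to see whether chance can be excluded, 100 in all with the real one. Where the real count was 0, all 100 divisions reach it by construction and nothing can be said of chance. This was so for miRNAs (100 and 100, highest others 23 and 27 in the tables labelled with and without size selection), all features (100 and 100, highest others 123 and 24) and the transcript lists of the second table (100, highest other 2). At an unadjusted p under 0.05, 69 and 37 divisions had at least the real 7 and 13 miRNAs, and 24 and 17 at least the real 635 and 85 features, so that chance cannot be excluded for these counts. It cannot be for the miRNA lists of the second table (20 of 100, real 3, highest other 5) or the transcript lists of the first (61 of 100, real 2, highest other 4). In the case of the miRNA lists of the first table, as many as the real 4 were called by 4 of 100 divisions, the real one included (highest other 4). That share is small taken alone, but it was the smallest of several, and other divisions reached the same count. All 4 calls were also lost with an estimated correlation (adjusted p = 0.245 to 0.394), so that chance is not excluded here either. Single lists there reached p values as small in 3 of 100 divisions for blood cell miRNAs, 9 for the miR-34 and miR-449 family, 12 for sperm transcripts, 13 for muscle transcripts and 14 for let-7 and for the X-linked cluster. In the second table they did in 8 for blood cell miRNAs, 5 for let-7 and 6 for the X-linked cluster. Divisions that called many features point to a structure of the samples: the 20 that put Control 9, Control 11 and MSUS 14 on 1 side called up to 23 and 27 miRNAs and up to 123 and 24 features, against at most 1 and 1 miRNAs and 16 and 14 features in the other 79. Because these libraries had both the most miRNA counts and low tRNA shares, depth and content are not told apart in that structure.

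Chance can be excluded for the differences between the tables, since of 40 exchanges of tables within animals only the real one reached 2217 features (1 of 40, highest other 1535), and of 100 only the real one reached 55 miRNAs (1 of 100, highest other 30). The interaction called 0, which all 100 divisions reach by construction (highest other 2), and 9 of 100 had at least its 23 miRNAs at an unadjusted p under 0.05, so that chance cannot be excluded for that count. The correlation of miRNA fold changes between the tables, 0.697, was reached by 30 of 100 divisions, with a median of 0.656 and a range of 0.393 to 0.864 over the others, so that it also arises in libraries divided without regard to MSUS. Scores of the lists, tested after their values were seen, gave adjusted p values of 0.135 or more over all lists, the smallest for inflammation-related miRNAs in the table labelled without size selection (−0.19, exact permutation p = 0.00794, adjusted p = 0.135). Sperm transcripts gave +0.45 in the other (exact permutation p = 0.0635, adjusted p = 0.422).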
